A study of Homo sapiens with 6 samples.

How the data were processed

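Total RNA was extracted with a column kit and treated with DNase, and libraries were made at a core facility by Illumina protocols, per the labels. Whether transcripts were selected by poly-A or ribosomal RNA was depleted is not given in the sources used here. The samples are 6 libraries of BT20, an established human triple negative breast cancer cell line, grown in serum-containing medium. Of these, 3 carry a control short hairpin RNA (shControl) and 3 carry a hairpin against cytokeratin 5 (shCK5-22), each in a knockdown vector. Groups and replicate numbers were taken from the sample titles. The labels give 1 hairpin per arm and name no batch, date or pairing.

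The authors deposited 1 table with a whole-number read count per gene symbol and library. Per the submitters' processing notes, the tools used included cutadapt, STAR, SAMtools and Cufflinks, with the genome build GRCh38. The tool that made the counts, its gene annotation, its use of strand and its handling of reads that map to several places are not given in the sources used here. A pair of near-identical ribosomal RNA precursor loci had nearly equal counts in every library, so reads that map to several places were either counted at each place or divided among them. Genes with near-identical copies, overlapping genes and antisense partners are therefore treated as uncertain.

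The table held 56505 rows. Of these, 27 had a calendar date in place of a gene symbol, the mark of a spreadsheet conversion, and were left out of library sizes and tests. They held between 0.167% and 0.175% of the counts of a library. The other 56478 rows had distinct symbols. Of those symbols, 37215 were found at 1 locus of GENCODE release 29 on GRCh38, 508 through an older symbol, 93 at several loci and 18662 were not matched. Coordinates and gene types come from that release, since the authors' annotation is not known. Older symbols were looked up in a RefSeq gene table of assembly GRCh38.p14, which was used for names only.

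Total counts were 47703937, 65541734 and 62688434 in shControl replicates 1, 2 and 3, and 64855513, 61078311 and 53121206 in shCK5-22 replicates 1, 2 and 3. A count of 3 in 1 library, taken as the floor, corresponds to between 0.0459 and 0.063 CPM, the count scaled by library size. These floors cover counting error only, since the reads carry no molecular identifiers.

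The comparison of shCK5-22 with shControl was fitted with edgeR 4.0.16 (R 4.3.3), in the quasi-likelihood test with robust estimation, TMM normalization and the filterByExpr filter on low counts. P-values are two-sided and were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Every adjusted p of a single gene comes from this test unless another tool is named. CPM values use TMM-scaled library sizes, SDs are over the 3 libraries of a group, and the standard error (SE) of a log2 fold change was derived from the fold change and its F statistic. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Libraries of a group were compared by a chi-square statistic per degree of freedom over genes with a joint count of at least 20, which lay between 3.47 and 4.88 for shControl pairs and between 5.08 and 33.7 for shCK5-22 pairs, so none was counted as a repeat of another.

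The gene lists, 25 in all, and the rules for named genes were fixed before the data were examined. The lists are basal keratins, simple epithelial keratins, luminal mammary markers, basal and progenitor mammary regulators, desmosome and hemidesmosome, adherens and tight junction, Wnt/beta-catenin targets, mesenchymal genes, extracellular proteases and inhibitors, epidermal differentiation and S100 genes, cell cycle, p53 targets, type I interferon response, antigen presentation, NF-kB cytokines and targets, immediate early genes, EGFR and MAPK output, YAP/TEAD targets, unfolded protein and integrated stress response, sterol and fatty acid synthesis, sphingolipid metabolism, hypoxia and glycolysis, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, and leukocyte, endothelial and fibroblast markers. All 719 genes written in the lists matched a symbol of the table, 3 of them through an older symbol. KRT5 was left out of every list. Lists were tested against all other genes with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 25 lists. The genes named are KRT5; the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups; and for each list the 2 members past the threshold with the largest change. Other members are given as further examples, and some genes are not reported here.

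The alternatives were other normalizations (RLE, upper quartile, library size only), no filter or a filter of at least 1 CPM in 3 libraries, an adjusted p threshold of 0.01, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, and for lists a correlation estimated from the data or the fry test. Fry tests whether the members of a list move, on balance, in 1 direction, and unlike camera does not compare them with other genes. An added alternative, chosen after seeing the data, left out ribosomal RNA precursor and mitochondrial rows. The fit was tested on simulated counts drawn from the means, library sizes and dispersions of this comparison, with 200 changed genes. Over 17746 genes, 48% of genes changed 1.25-fold, 62% of those changed 1.5-fold, 86% of those changed 2-fold and 98% of those changed 4-fold were recovered, and 17 of 17551 unchanged genes were called. Far more genes, 6153 of 18008, changed in the data, so these rates need not hold for the real comparison. A shift of 0.3 on the log2 scale placed on the p53 targets was recovered over 18008 genes, with 0 of the 24 other lists called. Simulated genes were drawn separately, without correlation between them, whereas the correlation estimated in the data reached 0.869 for ribosomal proteins. The simulation therefore cannot show how often correlated lists are called falsely.

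For the closing section, 3' UTRs of the longest protein-coding transcript per gene were taken from GENCODE 29, and each 7-base word was tested for association with lower log2 fold changes after regression of the fold changes, limited to 2 in either direction on the log2 scale, on UTR length and GC content. With shuffled residuals of 12888 genes, a word whose 604 carriers were lowered by 0.2 ranked 1 of all words. In the data the first-ranked word had a mean residual of only -0.068 over 1454 carriers. The simulation therefore does not show that a word of that size would be ranked first. These steps used Python 3.11.15 and numpy 2.4.6. The hairpin sequences are not given in the sources used here.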

Results

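RNA was sequenced from BT20 cells, a triple negative breast cancer line with basal features, that carried either a control hairpin (shControl, n = 3) or a hairpin against cytokeratin 5 (shCK5-22, n = 3). Cytokeratin 5, encoded by KRT5, is an intermediate filament protein of basal epithelial cells. Libraries held between 47703937 and 65541734 counts. After the filter on low counts, 18008 genes were tested. The single comparison in the design asks which transcripts change when KRT5 is knocked down in these cells.

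KRT5 (chromosome 12, 52514575 to 52520687, minus strand, GRCh38) was measured first, as the targeted gene. Its level was 230.7, 246.6 and 244.3 CPM in shControl replicates 1, 2 and 3, and 21.05, 22.7 and 24.09 CPM in shCK5-22 replicates 1, 2 and 3. These levels rest on 11088, 16085 and 15405 counts and on 1373, 1357 and 1273 counts. The mean fell from 241 ± 8.58 to 22.6 ± 1.52 CPM (SD, n = 3 each), a 10.7-fold lower level (log2 fold change -3.41, SE 0.0448, adjusted p = 1.23e-20). All 6 libraries therefore matched their labels.

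The knockdown libraries had lower levels of other basal keratins, type I interferon response genes and sterol synthesis genes. Inflammatory cytokine and NF-kB target genes were higher, and more mesenchymal genes rose than fell. In all, 6153 of the 18008 genes changed (34.2%), of which 3134 were higher and 3019 lower in shCK5-22. Most changes were small, with a median absolute log2 fold change of 0.29 among the changed genes. At least 2-fold differences were found for 641 genes, 291 higher and 350 lower, and a stricter filter of at least 1 CPM in 3 libraries left 347 of that size. The biological coefficient of variation was 5.01%. The groups did not overlap for 8121 genes (45.1%), where 10% is the share chance gives for 3 against 3.

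**Figure D1:**
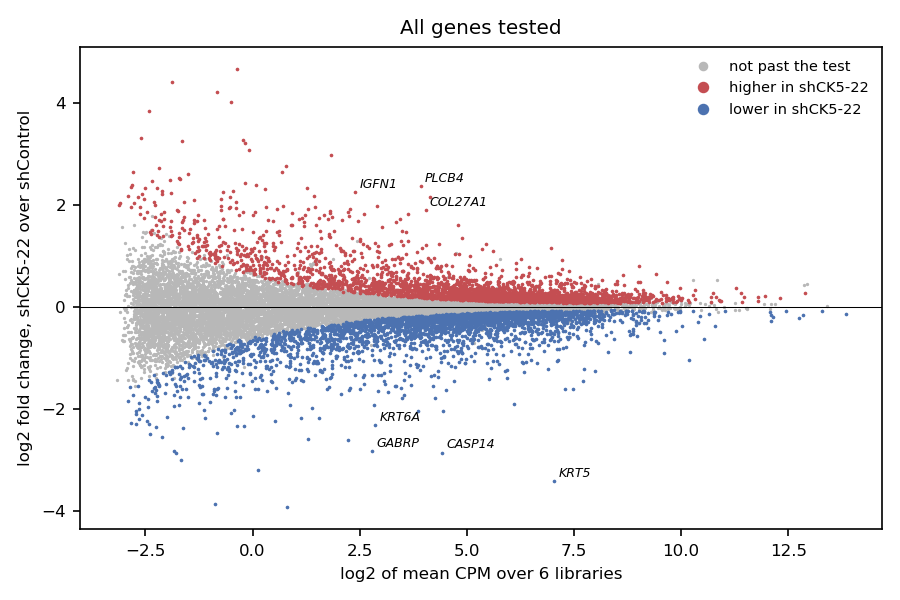
Log2 fold change of shCK5-22 over shControl against the log2 of the mean CPM over 6 libraries, 1 point per gene tested. Red points are the 3134 genes higher and blue points the 3019 genes lower in shCK5-22, and grey points did not pass the test.

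The 6 largest rises among well expressed genes included 2 collagens and a transcription factor of epithelial-mesenchymal transition. PLCB4, a phospholipase C (chromosome 20, 9068763 to 9481242), rose from 4.94 ± 0.557 to 25.5 ± 0.834 CPM, 5.14-fold (adjusted p = 2.93e-15). COL6A2, a collagen VI chain (chromosome 21, 46098097 to 46132849), rose 4.42-fold from 6.54 ± 0.931 to 28.9 ± 2.12 CPM (adjusted p = 7.68e-13). COL27A1, a fibrillar collagen (chromosome 9, 114155560 to 114312511), rose 3.7-fold from 6.98 ± 0.461 to 25.8 ± 1.16 CPM. ZEB1, a repressor of epithelial genes (chromosome 10, 31318495 to 31529814), rose 3.54-fold from 2.66 ± 0.0854 to 9.40 ± 0.849 CPM (adjusted p = 2.95e-11). IGFN1 (chromosome 1, 201190825 to 201228952) rose 4.74-fold and CHN1 (chromosome 2, 174799363 to 175005369), a Rac GTPase-activating protein, rose 3.92-fold.

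The 6 largest falls, KRT5 aside, held genes of epidermal, basal and interferon programs. CASP14, a caspase of epidermal cornification (chromosome 19, 15049384 to 15058293), fell 7.27-fold from 37.8 ± 0.11 to 5.19 ± 0.302 CPM (adjusted p = 4.56e-18). GABRP, a GABA receptor subunit expressed in basal-like breast cancers (chromosome 5, 170763350 to 170814047), was 7.08-fold lower, at 12.08 ± 0.556 and 1.71 ± 0.124 CPM (adjusted p = 2.06e-14). KRT6A (chromosome 12, 52487174 to 52493257) was 5.0-fold lower (adjusted p = 0.000248), a fold that is uncertain because its mRNA shares stretches with KRT5. RARRES1, a retinoid-responsive gene (chromosome 3, 158696892 to 158732696), was 4.13-fold lower (adjusted p = 1.23e-10). IFI44L, an interferon-induced gene (chromosome 1, 78619922 to 78646145), was 4.1-fold lower, from 35.0 ± 1.22 to 8.50 ± 0.606 CPM (adjusted p = 1.38e-15). FAM49A (chromosome 2, 16549459 to 16666331) was 3.81-fold lower (adjusted p = 6.77e-12).

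**Figure D2:**
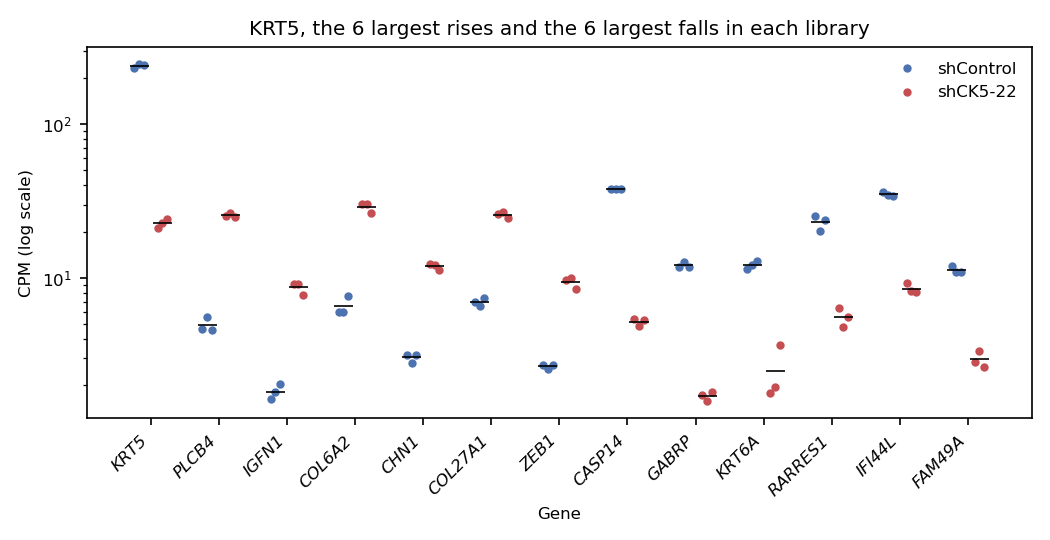
CPM on a log scale of KRT5, the 6 largest rises and the 6 largest falls, with 1 point per library (shControl blue, shCK5-22 red, n = 3 each) and a black line at each mean. The groups do not overlap for any of these genes, and KRT5 lies between 230.7 and 246.6 CPM in shControl and between 21.05 and 24.09 CPM in shCK5-22.

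All 7 basal keratins tested besides KRT5 were lower, 7 also adjusted over the list alone, with a median log2 fold change of -1.16 (camera, adjusted p = 3.67e-13). The call held with an estimated correlation (adjusted p = 0.0457 with an estimated correlation). KRT14, the partner of KRT5 in basal filaments, fell by 1.15 on the log2 scale, from 21.6 to 9.71 CPM, and KRT17 fell by 0.62, from 235 to 153 CPM. KRT6C (chromosome 12, 52468516 to 52473785) and KRT6A had the largest falls of the list, by 2.34 and 2.32. The KRT6 genes share sequence with one another, 35.5% of 50-base windows of KRT6C occurring in KRT6A, so the split of counts among them is uncertain. Of their windows, 2.87% for KRT6A and 3.79% for KRT6C occur in KRT5. These shares do not bound the reads the KRT6 genes could take from KRT5, which had far more counts. Exact stretches of at least 50 bases are still shared with KRT5. Direct pairing of the hairpin with KRT6 mRNAs was not tested, since its sequence is not given. KRT14, KRT16 and KRT17, which also fell, hold 0 such windows. The KRT6A count was at most 5.25% of the KRT5 count in shControl libraries and at least 8.52% in shCK5-22 libraries. For KRT6C these values were 0.64% and 0.81%. With the handling of shared reads unknown, KRT5 reads may account for part of the KRT6 falls, whose sizes are uncertain. KRT6C rests on 11 to 19 counts per shCK5-22 library.

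Of the 5 simple epithelial keratins tested, 3 fell and 0 rose, 3 and 0 adjusted over the list alone (median -0.37, adjusted p = 0.00207; adjusted p = 0.339 with an estimated correlation). KRT19 (chromosome 17, 41523617 to 41528308) fell from 1792 ± 91.9 to 1158 ± 60.8 CPM, by 0.63 on the log2 scale (adjusted p = 5.45e-08). KRT86 (chromosome 12, 52249300 to 52309163) fell by 0.91, but it is treated as uncertain, since reads it could share with similar hair keratin genes were not measured here. KRT8 and KRT18, the main simple keratin pair, stood at 3815 and 1627 CPM in shControl and at 3956 and 1699 CPM in shCK5-22 and did not pass the test. Epidermal differentiation and S100 genes fell too: 10 of 18 were lower and 0 higher, 10 also adjusted over the list alone (median -0.55, adjusted p = 1.98e-07; adjusted p = 0.0609 with an estimated correlation). The largest falls were those of KRT13 (chromosome 17, 41500981 to 41505705), by 1.73 on 5 to 34 counts per library, and of SPRR1A (chromosome 1, 152985231 to 152985500), by 1.59 on 14 to 75 counts. Better expressed members were SCEL, a cornified envelope precursor, lower by 1.52 in log2 terms at 12.7 and 4.45 CPM, and S100P and LCN2, both 1.34 lower.

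Among markers of both mammary lineages more fell than rose. Of 15 luminal markers 8 fell and 2 rose, the same numbers adjusted over the list alone (median -0.18, adjusted p = 0.00106; adjusted p = 0.0667 with an estimated correlation). CD24, a surface glycoprotein of luminal cells (chromosome 6, 106969831 to 106975627), fell from 1569 ± 50.1 to 760.7 ± 13.9 CPM, 2.06-fold (adjusted p = 1.49e-16), although near-identical copies make its count uncertain. FOXA1, a pioneer factor of luminal cells, fell by 0.79, and PRLR, the prolactin receptor (chromosome 5, 35048756 to 35230589), rose by 1.19 (adjusted p = 9.72e-06). Among 21 basal and progenitor regulators, 11 fell and 6 rose, as many as adjusted over the list alone (median -0.18, adjusted p = 0.00311; adjusted p = 0.0925 with an estimated correlation). MYLK, the myosin light chain kinase (chromosome 3, 123610049 to 123884331), rose by 0.99 from 22.5 to 44.7 CPM. ID1 (chromosome 20, 31605283 to 31606515) and ID3, inhibitors of differentiation, fell by 0.90 and 0.88, and the Notch pathway genes NOTCH3 and JAG1 by 0.82 and 0.64.

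Adherens and tight junction genes fell in 12 of 23 cases and rose in 2, 13 and 3 adjusted over the list alone (median -0.19, adjusted p = 0.00106; adjusted p = 0.16 with an estimated correlation). TJP3 (chromosome 19, 3708109 to 3750813) fell by 1.06, CLDN7 (chromosome 17, 7259903 to 7263983) by 0.56, the P-cadherin gene CDH3 by 0.47 and the E-cadherin gene CDH1 by 0.37. In the desmosome and hemidesmosome list 9 of 19 fell and 3 rose, with 9 and 3 adjusted over the list alone, and the list did not pass its test (median -0.08, adjusted p = 0.0716, between 0.0308 and 0.397 over the alternatives with camera). It passed without shControl replicate 1 (0.0474) and without shCK5-22 replicate 1 (0.0308). COL17A1, a hemidesmosome collagen (chromosome 10, 104031286 to 104085957), fell by 0.69 from 133.4 ± 6.37 to 82.6 ± 2.78 CPM, and PKP3 (chromosome 11, 392614 to 404908) by 0.41. The laminin chain gene LAMB3 rose by 0.26.

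Mesenchymal genes rose on balance, with 9 of 22 higher and 5 lower, 9 and 5 adjusted over the list alone (median 0.24, adjusted p = 5.1e-06; adjusted p = 0.0457 with an estimated correlation). CDH11, a cadherin of mesenchymal cells (chromosome 16, 64943753 to 65126112), rose 9.68-fold from a low level, with 4 to 16 counts per shControl library and 78 to 105 per shCK5-22 library. ZEB2 rose by 1.81, VIM, the vimentin gene, by 0.92 from 103 to 196 CPM, and COL6A1 by 1.24. Other members fell: TAGLN by 0.74 and TGFBI by 0.39. The fibronectin gene FN1 stood at 3005 and 2913 CPM and did not pass the test. Extracellular proteases and inhibitors fell in 11 of 22 cases and rose in 6, 12 and 6 adjusted over the list alone (median -0.10, adjusted p = 0.0362; adjusted p = 0.466 with an estimated correlation, 0.0671 without shCK5-22 replicate 2 and 0.0569 without shCK5-22 replicate 3, with a lowest value of 0.00333 over the alternatives with camera). Members went both ways: the matrix metalloproteinases MMP3 (chromosome 11, 102835801 to 102843803) and MMP9 (chromosome 20, 46008908 to 46016561) rose by 4.01 and 2.26. MMP3 had 2 to 8 counts per shControl library, and its log2 fold change was 4.76 without shControl replicate 1. The kallikreins KLK6 and KLK10 fell by 1.73 and 1.58.

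Targets of YAP and TEAD rose in 15 of 26 cases and fell in 5, 16 and 6 adjusted over the list alone (median 0.27, adjusted p = 0.00307; adjusted p = 0.0958 with an estimated correlation). ANKRD1 (chromosome 10, 90912096 to 90921276) rose 2.75-fold from 6.397 ± 0.712 to 17.7 ± 1.01 CPM and NUAK2 (chromosome 1, 205302059 to 205321791) 1.8-fold. F3, the tissue factor gene, fell by 0.65 from 952 CPM. Wnt/beta-catenin targets did not pass as a list, with 6 of 18 higher and 4 lower and 7 and 4 adjusted over the list alone (adjusted p = 0.847). Their median and mean were -0.01 while the test pointed up. LEF1 (chromosome 4, 108047545 to 108168956), a Wnt transcription factor, rose by 0.47 and BMP4 (chromosome 14, 53949736 to 53958761), a growth factor, fell by 0.47.

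Inflammatory and interferon genes moved in opposite directions. All 30 type I interferon response genes tested were lower in shCK5-22, 30 also adjusted over the list alone, with a median log2 fold change of -1.08 (adjusted p = 2.82e-160; adjusted p = 0.000977 with an estimated correlation). IFI44L fell by 2.04 and OAS1, a sensor of double-stranded RNA (chromosome 12, 112906777 to 112933222), by 1.64 from 11.6 ± 1.27 to 3.71 ± 0.834 CPM (adjusted p = 3.34e-08). Abundant members fell as well, ISG15 from 309 to 113 CPM and MX1 from 236 to 77.4 CPM. By contrast 24 of 26 NF-kB cytokines and targets rose and 2 fell, 24 and 2 adjusted over the list alone (median 0.89, adjusted p = 2.35e-24; adjusted p = 0.0061 with an estimated correlation). TNF (chromosome 6, 31575567 to 31578336) rose by 2.34 on 4 to 28 counts per library, and SAA1 (chromosome 11, 18266174 to 18269977), an acute phase gene with a near-identical neighbour and so uncertain, by 2.31. Better measured rises were those of TRAF1, by 1.60 from 13.7 to 41.8 CPM, BIRC3, by 1.09 from 31.2 to 66.4 CPM, CXCL8, by 1.21, and IL6, by 0.96. PTGS2, which encodes cyclooxygenase 2, and LIF were the 2 members that fell, by 1.12 and 0.33.

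Antigen presentation genes rose in 8 of 18 cases and fell in 3, 8 and 3 adjusted over the list alone (median 0.06, adjusted p = 0.0353). That call was lost with an estimated correlation (adjusted p = 0.294 with an estimated correlation), with the stricter filter (0.0815) and without shControl replicate 3 (0.0588), with a range of 0.0296 to 0.294 over the alternatives with camera. CD74, the invariant chain of class II complexes (chromosome 5, 150401637 to 150412929), rose by 0.67 from 33.1 ± 0.878 to 52.6 ± 1.14 CPM (adjusted p = 1.63e-10). CIITA, the class II regulator (chromosome 16, 10866222 to 10943021), rose by 1.09 (adjusted p = 0.0138), with groups that overlapped. Its adjusted p was 0.0782 without shControl replicate 2, 0.0726 without shCK5-22 replicate 1 and 0.0578 without shCK5-22 replicate 3, and lay between 0.00102 and 0.0782 over the alternatives. ERAP1, a peptide-trimming enzyme, rose by 0.60, and B2M fell by 0.19.

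Immediate early genes rose in 9 of 23 cases and fell in 4, 10 and 4 adjusted over the list alone (median 0.09, adjusted p = 0.00311; adjusted p = 0.125 with an estimated correlation). FOS (chromosome 14, 75278774 to 75282230) rose by 0.86 and KLF2 (chromosome 19, 16324817 to 16327874) by 0.80. EGFR and MAPK output genes went both ways, 7 of 25 higher and 10 lower, 7 and 10 adjusted over the list alone, and did not pass as a list (median -0.10, adjusted p = 0.314). EPGN, an EGFR ligand (chromosome 4, 74308473 to 74315307), fell 2.92-fold from 27.4 ± 0.747 to 9.39 ± 0.537 CPM (adjusted p = 1.11e-13). EREG, another ligand (chromosome 4, 74365143 to 74388751), fell by 0.69 (adjusted p = 0.0474), a call lost with library size only (0.0556), with no filter (0.0761) and when any library but shCK5-22 replicate 1 was left out (0.0846 to 0.143), with a range of 8.07e-05 to 0.143 over the alternatives. Cell cycle genes did not pass as a list, with 18 of 46 higher and 8 lower and 19 and 8 adjusted over the list alone (median 0.05, adjusted p = 0.0716, between 0.0308 and 0.61 over the alternatives with camera). The list passed without shControl replicate 2 (0.0414) and without shCK5-22 replicate 1 (0.0308). MYBL2 (chromosome 20, 43667019 to 43716496), a transcription factor of proliferating cells, rose by 0.48 and CDC25A (chromosome 3, 48157146 to 48188402), a cell cycle phosphatase, by 0.30. The p53 targets rose in 8 of 22 cases and fell in 1, 8 and 1 adjusted over the list alone, without passing as a list (median 0.10, adjusted p = 0.0716, between 0.0465 and 0.355 over the alternatives with camera), although it passed without shControl replicate 2 (0.0465). GDF15 (chromosome 19, 18374731 to 18389176) rose by 1.18 from 0.855 to 1.93 CPM and BBC3 (chromosome 19, 47220822 to 47232766) by 0.40.

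Sterol and fatty acid synthesis genes fell almost throughout: 29 of 33 were lower and 0 higher, 30 and 0 adjusted over the list alone (median -0.39, adjusted p = 1.24e-27; adjusted p = 0.0457 with an estimated correlation). TM7SF2, a sterol reductase (chromosome 11, 65111845 to 65116384), fell 2.1-fold. SCD, the stearoyl-CoA desaturase, fell from 1015 to 543 CPM, FASN, the fatty acid synthase, from 1092 to 780 CPM, and SREBF1, a transcription factor of the pathway, from 150 to 88.5 CPM. Sphingolipid genes did not pass as a list, with 12 of 39 higher and 5 lower, 14 and 5 adjusted over the list alone (median 0.05, adjusted p = 0.237). ST3GAL5, the GM3 synthase (chromosome 2, 85837120 to 85905199), rose 3.28-fold and CERS4, a ceramide synthase (chromosome 19, 8206736 to 8262421), fell 2.36-fold.

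Hypoxia and glycolysis genes showed no common direction, with 6 of 33 higher and 9 lower, 6 and 9 adjusted over the list alone (median -0.05, adjusted p = 0.696). CA9, a carbonic anhydrase (chromosome 9, 35673856 to 35681159), fell by 1.11 and ANGPTL4 (chromosome 19, 8363289 to 8374373) rose by 1.05. Stress response genes split evenly, 12 of 34 higher and 10 lower, 13 and 12 adjusted over the list alone, and did not pass as a list (mean 0.06, adjusted p = 0.195). Their median lay between -0.014 and 0.006 depending on the scaling. PPP1R15A (chromosome 19, 48872392 to 48876057), a phosphatase subunit of the integrated stress response, rose by 0.74 from 112.5 ± 3.13 to 188 ± 2.51 CPM. DDIT3 (chromosome 12, 57516588 to 57521737) rose by 0.68 (adjusted p = 0.015), a call lost without shControl replicate 2 (0.0603) or 3 (0.102), with a range of 0.00364 to 0.102 over the alternatives.

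Mitochondrially encoded mRNAs were slightly lower, 10 of 13 with 2 higher, 10 and 2 adjusted over the list alone (median -0.11, adjusted p = 0.0353). That call was lost with an estimated correlation (adjusted p = 0.606 with an estimated correlation), with the stricter filter (0.0753), without shControl replicate 2 (0.0733) and without shCK5-22 replicate 3 (0.0525), with a range of 0.0115 to 0.606 over the alternatives with camera. MT-ND6 (mitochondrial genome, 14149 to 14673) fell by 0.38 and MT-ND5 (12337 to 14148) by 0.28. Mitochondrial rows took between 7.27% and 7.52% of the counts in shControl and between 6.75% and 6.9% in shCK5-22. Ribosomal protein genes were slightly higher as a list, 12 of 70 with 0 lower and 58 that did not pass, 10 and 0 adjusted over the list alone (median 0.07, adjusted p = 0.0353). Of all 18008 genes tested 3134 were higher, a like share. Up to 3 members were lower under another scaling, and the list did not pass in fry (adjusted p = 0.358). Their call was lost with an estimated correlation (adjusted p = 0.783 with an estimated correlation), with the stricter filter (0.0815), and without shControl replicate 3 (0.15), shCK5-22 replicate 2 (0.379) or shCK5-22 replicate 3 (0.0696). Over the alternatives with camera the adjusted p lay between 4.18e-07, without shCK5-22 replicate 1, and 0.783. RPL6 (chromosome 12, 112405190 to 112418838) rose by 0.23 and RPL7 (chromosome 8, 73290267 to 73295789) by 0.18, both with many processed copies in the genome and so uncertain.

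Markers of leukocytes, endothelium and fibroblasts did not pass as a list, with 3 of 15 higher and 3 lower, 3 and 3 adjusted over the list alone (adjusted p = 0.544). The median was -0.01 while the mean was 0.33 and the test pointed up. PDGFRB, a growth factor receptor of fibroblasts (chromosome 5, 150113837 to 150155872), rose by 4.22 from 0, 6 and 4 counts to 80, 46 and 66 counts, and by 4.84 without shControl replicate 2. LUM, the lumican gene (chromosome 12, 91102629 to 91111831), rose by 1.85 on 4 to 26 counts per library. Other fibroblast and endothelial markers went the opposite way, as FAP fell by 0.86 and PECAM1 fell from 5.02 ± 1.66 to 2.15 ± 0.728 CPM (adjusted p = 0.0429).

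**Figure D3:**
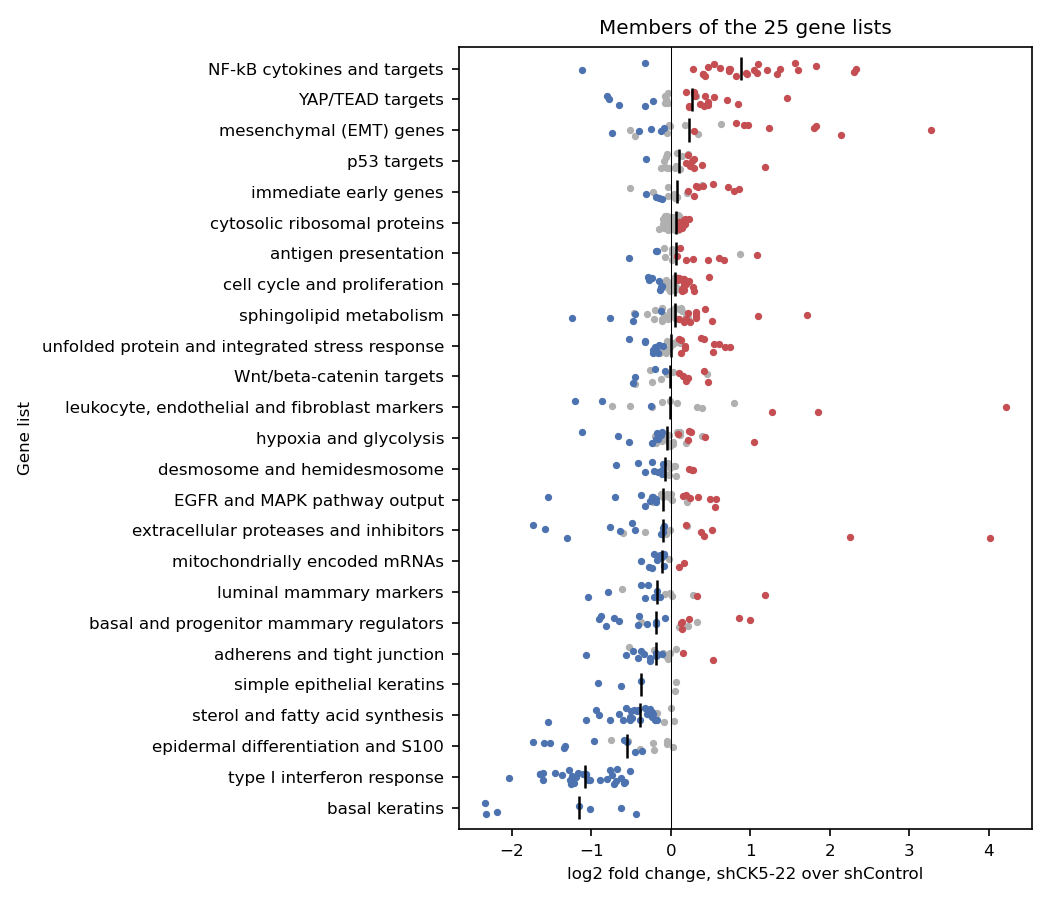
Log2 fold change of shCK5-22 over shControl for each member of the 25 gene lists, ordered by the median of the list (black line). Red and blue points are members that rose or fell and grey points did not pass the test; all 30 interferon genes lie below 0, and 24 of 26 NF-kB cytokines and targets lie above 0.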

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

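The test of the date rows was chosen after the main results were seen. The rows with a calendar date in place of a gene symbol entered no comparison of the report, since a date can stand for more than 1 gene. Of these 27 rows, 22 passed the filter on low counts when fitted together with all other genes. Among them 6 changed between shCK5-22 and shControl, 3 higher and 3 lower, with a largest absolute log2 fold change of 1.07. The genes behind them are not named here. No biological explanation was tested for them.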

How the results depend on the processing

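Leaving out the ribosomal and mitochondrial rows was the only alternative chosen after the data were seen. KRT5 kept its direction and its call in all 15 alternatives, with a log2 fold change between -3.46 and -3.36, a range also reached by leaving out single libraries. The count of changed genes lay between 4910 and 6185 when each library was left out in turn, and the count changed at least 2-fold between 579 and 649. The other normalizations, the filters, DESeq2 and limma-voom gave between 5520 and 6289 changed genes, a threshold of 0.01 gave 4382, and the share of changed genes that were higher lay between 46.8% and 52.7%. The median over all genes moved by at most 0.02. A filter of at least 1 CPM in 3 libraries lowered the count changed at least 2-fold from 641 to 347, as it tests 13636 genes and removes low ones. Of the 25 lists, 16 passed in the main setting, between 13 and 18 without single libraries, 13 with the stricter filter and 15 without ribosomal and mitochondrial rows, which leaves no mitochondrial list to test. Fry, which asks a different question since it does not compare a list with other genes, gave 20, a count not comparable with these. Several lists that did not pass in the main setting passed in fry. They were desmosome and hemidesmosome (fry adjusted p = 0.00293), stress response (0.00357), p53 targets (0.0054), sphingolipid metabolism (0.0139) and cell cycle (0.0396). Ribosomal proteins passed in the main setting and not in fry. With an estimated correlation 5 passed: basal keratins, mesenchymal genes, interferon response, NF-kB targets and sterol synthesis; the cause was not tested. For each of the 11 lists that lost their call this way, that adjusted p was the highest of its camera alternatives. Among 60 named genes, 57 kept their call in every alternative run, 3 (CIITA, EREG and DDIT3) lost it in some, and 0 values reversed. The labels name no pairing, and the replicate numbers gave no clear sign of it, though these values cannot settle it. The correlations of deviations between same-numbered libraries were 0.016, 0.052 and -0.007, and not every library correlated best with its own number. With the number as a replicate block, 6743 genes changed, 644 of them at least 2-fold, KRT5 had a log2 fold change of -3.41, and 16 lists passed, with no list or named gene losing or gaining its call. Depth limits the genes with few counts, such as PDGFRB, MMP3, TNF, LUM and KRT13, whose folds are imprecise.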

Other observations

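All tests below but that of other splits were chosen after the main results were seen, and only for seed words as a main or minor source and for direct pairing with PDHA1 were the bounds set before the tests were run.

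Among 162 groups of at least 10 protein-coding genes that share a symbol stem, 7 passed in camera (the stems KRT, COL, CASP, PARP, CT, IL and SEMA), and none held with an estimated correlation (adjusted p = 0.995 for each). Several members, such as KRT6A, IL6 and PARP9, are also in the lists above, so these groups are not separate from those results. Of 20 keratin genes besides KRT5, 16 fell and 0 rose (median -0.90, adjusted p = 3.85e-11), among them KRT9, which is in none of the lists, from 7.79 to 4.71 CPM. Of 33 collagen genes 15 rose and 5 fell (adjusted p = 0.000124). COL8A1 rose by 0.98 from 7.12 to 14.1 CPM, COL7A1, the anchoring fibril collagen, by 0.69, and COL18A1 by 0.59, while COL4A6, a basement membrane chain, fell by 0.29. Genes with the stem IL, mostly interleukins and their receptors, rose in 18 of 51 cases and fell in 6 (adjusted p = 0.0188). IL24 rose by 1.84 from 1.54 to 5.46 CPM and IL6R, the interleukin 6 receptor, by 1.35 from 16.5 to 42.3 CPM, while IL1RN, the interleukin 1 receptor antagonist, fell from 4.29 to 1.78 CPM. Semaphorin genes fell in 6 of 17 cases and rose in 2 (adjusted p = 0.0409), led by SEMA3B, lower by 1.40 on the log2 scale at 89.2 and 33.7 CPM. Of 12 genes with the stem CASP, caspases and the caspase-associated CASP8AP2, 6 fell and 1 rose (adjusted p = 0.000213), with CASP10 from 16.6 to 9.49 CPM beside CASP14. Of 12 genes with the stem PARP 5 fell and 2 rose (adjusted p = 0.0011), PARP9 from 114 to 47 CPM and PARP14 from 176 to 99.1 CPM. Of 10 cancer/testis genes with the stem CT 7 fell and 0 rose (adjusted p = 0.0035), but most are near-identical CT45A copies and so uncertain. None of these family medians changed sign with the scaling.

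Genes lower in shCK5-22 carried a short sequence of the KRT5 mRNA in their 3' UTRs more often than other genes. Of all 16384 words of 7 bases, the 3 most associated with lower levels were CCAGTCA (z = -6.86), CAGTCAA (z = -6.23) and ACCAGTC (z = -4.52). They overlap in ACCAGTCAA, which occurs 1 time in KRT5, in the coding sequence of exon 8 of 9 (chromosome 12, 52515803 to 52515811, minus strand, GRCh38). The next word had z = -3.87 and the lowest of 100 shuffles was -4.82. Only ACCAGTC sets this site apart, and its z did not pass the lowest shuffle. CCAGTCA and CAGTCAA form CCAGTCAA, which occurs 2 times in KRT5, so the site is not settled. A hairpin aimed at either copy of CCAGTCAA, with off-target pairing through its seed, is a candidate explanation for part of the falls. Of 1454 genes holding CCAGTCA 428 were lower and 277 higher (median log2 fold change -0.041), against 2054 lower and 2561 higher of 11434 others (median 0.015). The word was chosen from these same fold changes, so the counts describe its size and add no separate support. Direct pairing through any single KRT5 word as the main source is argued against by the largest excess among fallen over unchanged genes. It was 7.6 percentage points, over the 82.2% of fallen genes with a 3' UTR searched. Words of the other strand of the hairpin were not searched, and falls that follow from an off-target gene need hold no word. Seed pairing as an indirect source of most falls is therefore not decided. In the comparison with 1000 other mRNAs, 84% had a weaker best word. By the bound of 95% set before the test, this value counted against seed words as a minor source. However, the other 16% carry CCAGTCA themselves, so that a percentile of 95 was out of reach. The bound set before made no allowance for this, and no conclusion is drawn from the comparison. Knockdown of KRT5 itself and indirect off-target effects both stay open for the rest.

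PDHA1, a subunit of pyruvate dehydrogenase (chromosome X, 19343893 to 19361705, GRCh38), was singled out after its values were seen, since it fell from 109 ± 1.82 to 29.2 ± 0.318 CPM (SD, n = 3 each), by 1.90 on the log2 scale (adjusted p = 9.31e-19), with little spread. Near-perfect pairing of the hairpin with its mRNA is argued against, as its longest exact run shared with KRT5 was 11 bases, where the median of 1000 other mRNAs was 12, and its closest 19-base window had 3 mismatches, the median of 200 others. Its 3' UTR holds the 8-base match CCAGTCAA, and PDHA1 was the lowest of the 277 genes that do. The median of those genes was only -0.051, so whether the match may account for the fall of PDHA1 cannot be told apart from a response to lower KRT5. Other fallen genes with the match were RDH10, by 1.76, and ZNF365, by 1.15 on the log2 scale.

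The fall of all 30 interferon response genes was weighed against 3 technical explanations. A bias of GC content or length is argued against, since the list's median was -1.102 after regression of all genes on both, where the median absolute deviation of all residuals was 0.161. Direct seed matches through CCAGTCA are argued against as well. Of the members 3.3% (1 of 30) hold CCAGTCA in the 3' UTR, and the other 29 had a median of -1.102. Other words of the hairpin, whose sequence is not given, were not checked on this list. An interferon response raised by the control hairpin or vector, and not lowered with KRT5, cannot be told apart from an effect of the knockdown, because the design has 1 hairpin per arm. A biological link between KRT5 and this response stays open as well, untested.

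The count of changed genes was also taken for other groupings of the libraries. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many as 6153, the real one, and the highest of the others gave 0. No conclusion is drawn, since 10 splits are too few for a share under 0.05. Every other split also mixes both groups on each side, so the real difference widens the spread within sides and lowers the calls. On the second principal component, which held 14.4% of the variance, shCK5-22 replicate 1 lay at 30.4 and the other libraries of its group at -16 and -13.4. Its chi-square per degree of freedom was 33.7 against shCK5-22 replicate 2 and 19.77 against replicate 3. Replicates 2 and 3 had 5.08 between them, and pairs between the groups lay between 40.08 and 56.91. Reads of a ribosomal RNA precursor locus numbered 340755 of 64855513 counts in shCK5-22 replicate 1. They numbered 702176 of 61078311 and 529542 of 53121206 in shCK5-22 replicates 2 and 3. In shControl replicates 1, 2 and 3 they numbered 311037 of 47703937, 445155 of 65541734 and 418838 of 62688434. As a share of counts, shCK5-22 replicate 1 lay below every shControl library, and shCK5-22 replicates 2 and 3 lay above them. Without shCK5-22 replicate 1, 6185 genes changed.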
